A study of Mus musculus with 8 samples.

How the data were processed

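Mouse bone marrow cells of strain C57BL6/J were profiled on Affymetrix arrays, 1 array for each of 8 groups. The groups were 4 cultures sampled on days 3 and 6 after the start of treatment: M-CSF, M-CSF+RANKL, PSS1-WT and PSS1-LMS. M-CSF was used at 50 ng/ml and RANKL at 100 ng/ml, and the PSS1 cultures received both factors and, a day later, a retrovirus for wild-type or mutant PSS1. Per the labels, biotinylated cDNA was made from 500 ng of total RNA per array. The labels do not say whether the M-CSF and M-CSF+RANKL cultures received an empty vector.

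The deposited table holds log2 signals for 28846 features, of which 22142 are transcript clusters. How the authors summarised probes and normalised the arrays is not given in the sources used here. That the values are on the log2 scale was read from the values themselves. They ran from 1.25 to a ceiling that equals log2 of 1000000, and the array medians over all features lay between 4.80 and 4.93. They were used as deposited. The 23 background probe sets, which match no mouse transcript, reached between 5.54 and 7.13 depending on the array.

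A single gene symbol was attached to 19572 clusters, which represented 19505 genes. For the 55 genes with several clusters, the cluster with the highest mean over the 8 arrays was used. A gene counted as measured when the highest of its 8 values reached 4.86, the 50th percentile of the table, which left 10871 genes. The 2615 clusters without a symbol were kept out of the gene comparisons and are described apart. The mutation carried by PSS1-LMS and the species of the PSS1 insert are not given in the labels.

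The comparisons were M-CSF+RANKL minus M-CSF (RANKL effect), PSS1-WT minus M-CSF+RANKL, PSS1-LMS minus M-CSF+RANKL, PSS1-LMS minus PSS1-WT, and day 6 minus day 3. A difference on a single day rests on 1 array per side and was not tested. The tested quantity was the difference averaged over days 3 and 6, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with culture and day as additive terms. The RANKL and day effects used all 8 arrays, with 3 residual degrees of freedom, and the PSS1 comparisons used the 6 arrays with RANKL, with 2. P-values were adjusted by the Benjamini-Hochberg method over the 10871 genes, and 0.05 was the threshold. Their error is the part of the culture differences that changed between the 2 days, over all arrays in the fit. For the day effect it is how far the day difference varied between the 4 cultures. Neither covers spread over separate animals or replicate cultures. eBayes pools each gene's variance with that of all genes. The pooled part had 4.71 degrees of freedom for the RANKL and day effects and 13.3 for the PSS1 comparisons. A p-value of a PSS1 comparison thus rests mostly on spread shared by all genes, not on the gene's own. Errors are standard errors from the limma fit. Where the signals on the low side lay within the background of their arrays, on 1 day or both, the fold was computed against that background and is given as "at least"; where both sides did on both days, no fold is given. Log2 differences are given as measured.

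The test was checked on simulated data with 50 changed genes per fold size among 10871. It recovered 78% of 4-fold changes in the RANKL comparison, 98% in the day comparison and 100% in each of the 3 PSS1 comparisons. At 2-fold it recovered 4%, 28%, and between 62% and 74%. Noise was simulated independently for each gene, without shifts shared by a whole array. Far fewer genes were changed than passed with RANKL, so the recovery there need not hold for the real comparison. Unchanged genes made up 6 of 96 calls for RANKL, 2 of 141 for PSS1-WT, 19 of 164 for PSS1-LMS, 9 of 143 for PSS1-LMS against PSS1-WT and 13 of 127 for day, over the share of 0.05 that the threshold allows on average in all but PSS1-WT; each is from 1 simulated data set.

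A total of 31 gene lists with 482 genes covered osteoclast functions, other cell types of bone marrow, phospholipid and sterol metabolism, and stress, cytokine, cell cycle and energy pathways. Each list is summarised by the median log2 difference of its measured members and its percentile among 10000 random lists of equal size, matched on mean expression in 20 bins. This percentile is a description, not a test, since members of a list vary together. In simulations that drew every gene independently, 6% of unrelated 15-gene lists fell outside the central 95% range. They thus leave out members that vary together. Members past the limma threshold were counted after adjustment over all genes and after adjustment over the list alone. A second median was computed with every signal at or under 7.13, the brightest background probe set on any array, raised to that value; it is called the floored median, and it was chosen after the data were seen. Where list members are counted as within background, 7.13 is the limit. It exceeds the brightest background probe set of each array with RANKL. Genes at least 2-fold higher or lower with RANKL were also followed into the PSS1 cultures, each measured on arrays that had not served to choose them.

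The groups, comparisons, tests, gene lists, naming rule and all alternatives except the floored medians were fixed before the data were examined; the tests of explanations were written later, some of them after the result was seen. The rule named, in each culture comparison, the 6 genes with the largest mean difference in each direction among genes at least 2-fold apart in the same direction on both days. In the day comparison it named the 6 per direction among genes at least 2-fold apart in all 4 cultures. It always named Ptdss1, Ptdss2, Pisd, Acp5, Ctsk, Mmp9, Nfatc1, Dcstamp, Ocstamp, Calcr, Atp6v0d2, Itgb3, Oscar, Csf1r and Irf8, another gene that is not reported here, and up to 4 members with the largest differences in each list described. Predicted genes, immunoglobulin and T cell receptor segments and small RNA genes were counted but not named.

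The alternatives were quantile normalisation, centring on array medians, no filter, a filter at the 70th percentile, a filter on the mean of the compared arrays, the mean of all clusters of a gene, fold thresholds of 1.5 and 4, eBayes with a trend, leaving out the day or culture term, other sets of arrays in the fit, and leaving out each array in turn. Each day alone was tried for the list medians. An offset of 32 planned for linear values was not run because the values were already log2.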

Results

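Transcript levels were measured in cultures of mouse bone marrow cells on 8 arrays. M-CSF is the growth factor that drives bone marrow precursors towards macrophages, and RANKL is the cytokine that turns such precursors into bone-resorbing osteoclasts. PSS1, encoded by Ptdss1, is phosphatidylserine synthase 1, which makes phosphatidylserine from phosphatidylcholine. LMS is the usual abbreviation of Lenz-Majewski syndrome, a disorder with dense bone caused by mutations in that gene; the labels call the insert mutant and do not spell the name out. Each of the 8 groups, 4 cultures on 2 days, was 1 array, so no group has a replicate and the number of arrays limits the precision of every value.

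The arrays separated first by RANKL. Over the 10871 measured genes, the first principal component held 75.7% of the variance and set the 2 M-CSF arrays apart from the 6 arrays with RANKL. Correlations across genes ran from 0.982 to 0.993 between arrays with RANKL and from 0.832 to 0.889 between an array with RANKL and one without, and the M-CSF arrays of days 3 and 6 correlated at 0.942. Genes are not independent replicates, so these values describe likeness only.

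The first comparison asked which transcripts RANKL changed in cells kept with M-CSF. The resorption genes Mmp9, Ctsk and Acp5 rose from background to signals close to the ceiling of the scale. Mmp9, a gelatin- and collagen-cleaving protease, rose by 15.18 ± 0.35 in log2 units averaged over both days, at least 7377-fold. Ctsk, the protease that degrades bone collagen, rose by 14.84 ± 0.34, at least 8996-fold, and Acp5, the tartrate-resistant acid phosphatase used to stain osteoclasts, by 14.15 ± 0.38, at least 9417-fold. Macrophage genes fell: C1qa, a chain of complement C1q, was at least 331.5-fold lower (log2 difference -8.80 ± 0.62), and Ly86, a partner of the receptor Cd180, 463-fold lower (-8.85 ± 0.39).

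The other genes named for the largest rises were Akr1c18, a steroid dehydrogenase (at least 1813-fold), Ocstamp, needed for the fusion of osteoclast precursors (at least 292-fold), and Oscar, an osteoclast receptor that signals through an ITAM adaptor (at least 245-fold). Dcstamp, a second fusion gene, rose at least 1014-fold, the integrin subunit Itgb3 at least 228-fold, and the calcitonin receptor Calcr at least 141-fold. Nfatc1, the transcription factor that drives osteoclast formation, rose 31.6-fold (4.98 ± 0.68, adjusted p = 0.00135). Atp6v0d2, a proton pump subunit of osteoclasts, rose at least 807-fold (10.69 ± 1.88, adjusted p = 0.00466), with a difference of 14.94 on day 3 and 6.44 on day 6, because its signal in the M-CSF culture went from 4.23, within background, to 12.55. The other genes named for the largest falls were Fcrls, a receptor-like gene of macrophages (at least 201-fold lower), Gpr65, a proton-sensing receptor (at least 289-fold), and the C1q chains C1qc (312-fold) and C1qb (288-fold). Irf8, a transcription factor that restrains osteoclast formation, fell (-2.46, adjusted p = 0.00128; at least 1.94-fold). The M-CSF receptor gene Csf1r did not pass (-0.73, adjusted p = 0.155). Of the phosphatidylserine enzymes, Ptdss2 rose (1.26 ± 0.34, adjusted p = 0.0301), and Ptdss1 (-0.36, adjusted p = 0.646) and the decarboxylase Pisd (0.51, adjusted p = 0.544) did not pass.

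**Figure D1:**
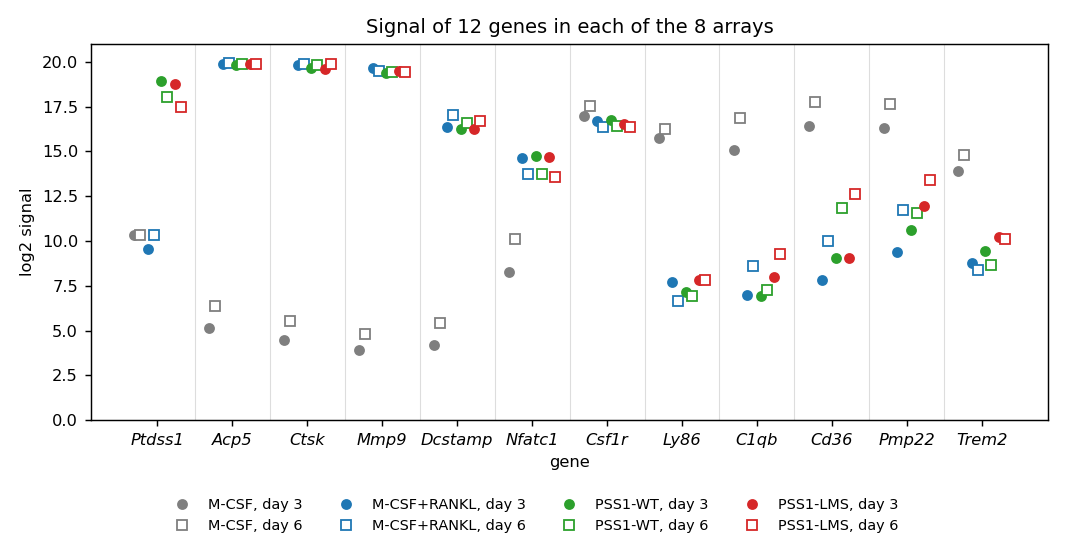
Log2 signal of 12 genes in each of the 8 arrays, with colour for the culture and filled circles for day 3, open squares for day 6. Ptdss1 lay at 17.50 or above in the PSS1 arrays and at 10.36 or below in the others; Acp5, Ctsk, Mmp9 and Dcstamp separated the arrays with RANKL from the M-CSF arrays, and Ly86, C1qb, Cd36, Pmp22 and Trem2 lay highest in the M-CSF arrays.

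Among the osteoclast lists, 13 of 15 resorption genes rose and none fell (14 adjusted over the list alone; median difference 5.74, percentile 100, floored median 5.35), with Car2, the carbonic anhydrase that supplies protons, at 11.68. Of 12 fusion and adhesion genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone; median 3.92, percentile 100, floored 2.58); the kinase gene Src rose by 7.53, and Adam8 (-3.56) and Cd47 (-1.10) fell. Of 19 RANK signalling and transcription factor genes, 9 rose and 1 fell, also when adjusted over the list alone (median 1.37, percentile 99.98, floored 1.27): Jdp2 rose by 9.81, Fosl2 by 6.37, Ppargc1b by 6.03 and Fos by 5.57, and Nfatc2 fell (-2.98). Of 16 vacuolar ATPase genes, which acidify lysosomes and the resorption space, 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 3.08, percentile 100): Atp6v1d rose by 4.79 and Atp6v1b2 by 3.82, and Atp6v0a1 fell (-4.74). Of 8 coupling factor genes, through which osteoclasts signal to osteoblasts, 5 rose and 1 fell, also adjusted over the list alone (median 3.04, percentile 100, floored 1.13): Efnb2 (6.58), Pdgfb (4.94), Lif (4.71), Sema4d (3.89) and Sphk1 (2.19) rose, and Hgf (-3.68) fell. In the ITAM costimulation list of 8 genes Oscar rose and 5 fell, also adjusted over the list alone (median -1.92, percentile 0, floored -0.17): Fcgr3 (-7.33), Trem2 (-5.78), Pilrb1 (-2.20), Fcer1g (-1.96) and Fcgr4 (-1.89). Of 14 osteoclast inhibitor genes, 6 fell and 1 rose (8 and 1 adjusted over the list alone; median -1.74, percentile 0, floored -0.57): Dok2 (-3.62), Rbpj (-3.50) and Bcl6 (-2.64) fell, Dok1 rose by 1.501, and Id2 did not pass (-2.89, adjusted p = 0.0761). Of 15 calcium signalling genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone; median -0.31, percentile 6.83, mean 0.00 and floored median 0.00). Rcan1 (4.40) and Rcan2 (2.70), inhibitors of calcineurin, rose; Trpv4 (-2.45), Orai1 (-1.38) and Stim1 (-1.06), all of calcium entry, fell. List members named beyond the 4 largest of their list were chosen after their values were seen, because the count they belong to was 5 or fewer.

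Of the other cell types, 14 of 15 macrophage markers fell and none rose, also adjusted over the list alone (median -5.32, percentile 0, floored -4.40). In the dendritic cell and MHC class II list of 7, Itgax (1.45), H2-Aa (1.34) and H2-Eb1 (1.30) rose and H2-DMa did not pass (-1.42, adjusted p = 0.0609); 3 rose and 1 fell adjusted over the list alone (median 1.003, percentile 99.4). Its floored median was 0.00, with 4 of 7 members within background in every array compared. Of 12 neutrophil markers, Mmp8 (-4.66) and Csf3r (-3.75) fell and 1 fell adjusted over the list alone; the median was 0.23 (percentile 85.7, floored 0.00) and the mean -0.40, of opposite sign. The platelet gene Pf4 (-8.17) alone fell among 5 megakaryocyte, mast cell and basophil markers (1 adjusted over the list alone; median -0.51, percentile 18.5, floored 0.00). None of 5 stromal and osteoblast markers passed by limma, in either adjustment (median -0.11, percentile 47.5, floored 0.00). The B cell, erythroid and T and NK cell lists each had 1 measured member. Blnk, of the B cell list, fell (-2.34), also adjusted over the list alone; Slc4a1 (-0.61) and Cd4 (-0.87) did not pass in either adjustment.

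In lipid metabolism, 10 of 18 cholesterol synthesis genes fell and none rose (12 adjusted over the list alone; median -1.48, percentile 0), led by Sqle (-3.33), Fdft1 (-3.23), Fdps (-2.94) and Cyp51 (-2.89). Of 10 fatty acid synthesis genes 5 fell, also adjusted over the list alone (median -1.78, percentile 0.01, floored -1.09): the desaturases Fads2 (-6.21), Fads1 (-5.78) and Scd1 (-1.86), Elovl6 (-3.41) and Me1 (-2.28). Of 8 LXR targets, genes of lipid metabolism, Mylip (-4.42), Apoe (-4.16) and Smpdl3a (-2.76) fell and Nr1h3 rose by 1.49, also adjusted over the list alone. The median of -1.498 (percentile 0.13) came from day 6 at -3.36, against 0.20 on day 3. Of 13 genes of phosphatidylserine and phosphatidylethanolamine synthesis 4 rose, also adjusted over the list alone (median 0.19, percentile 65.1, floored 0.00): Pcyt1a (2.57), Chpt1 (2.17), Selenoi (1.48) and Ptdss2. Of 12 flippase and scramblase genes, which move phosphatidylserine between membrane leaflets, 5 fell and 1 rose, also adjusted over the list alone (median -0.78, percentile 0.89, floored -0.51): Atp8b4 (-3.95), Atp8a1 (-2.43), Plscr4 (-1.73), Atp11a (-1.63) and Plscr3 (-1.27) fell, and Xkr8 rose by 1.70. Of 11 genes for recognition of phosphatidylserine on dying cells, 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -3.62, percentile 0, floored -2.93). The receptor Cd36 (-8.17), the bridging protein Gas6 (-7.52), Stab1 (-7.46) and the kinase Mertk (-6.12) fell, and Mfge8 rose by 3.80.

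Among the pathway lists, 20 of 21 mitochondrial respiration genes rose and none fell (21 adjusted over the list alone; median 2.84, percentile 100): Mdh2 by 4.42, Idh3a by 4.34, Uqcrc2 by 3.65 and Cycs by 3.42. Of 24 cell cycle genes 12 fell and none rose (16 adjusted over the list alone; median -1.497, percentile 0, floored -1.47), with Nusap1 (-2.55), Tpx2 (-2.47), Pcna (-2.46) and Aurkb (-2.30). Of 16 interferon-stimulated genes 8 fell (9 adjusted over the list alone; median -1.65, percentile 0), with Oasl2 (-4.21), Stat2 (-3.95), Bst2 (-3.37) and Ifih1 (-2.69); the floored median was 0.00, with 10 of 16 members within background throughout. Of 15 integrated stress response genes 5 rose and 1 fell (8 and 2 adjusted over the list alone; median 1.18, percentile 99.99, floored 0.46): Asns (3.87), Mthfd2 (2.71), Atf4 (2.01), Aldh18a1 (1.97) and Shmt2 (1.93) rose and Atf3 (-3.23) fell. Of 15 unfolded protein response genes Edem1 rose by 0.93 and Sdf2l1 fell (-1.15), and 0 passed adjusted over the list alone, by limma, against these 2 over all genes (median -0.19, percentile 10.8, mean 0.01, of opposite sign). Of 10 inflammatory genes 3 rose and 2 fell, also adjusted over the list alone: Il1rn (6.61), Tnfaip3 (4.99) and Nfkbia (4.38), which restrain inflammation, rose, and the chemokines Ccl3 (-4.97) and Ccl4 (-2.02) fell. Their median was -1.45 (percentile 0.06, floored -0.43), and 0.29 on day 6 alone. Of 17 lysosome genes 3 rose and 5 fell (4 and 5 adjusted over the list alone; median 0.39, percentile 60.8, mean -0.24, of opposite sign): Cd63 (1.72), Npc2 (1.67) and Ctsz (1.54) rose, and Lamp2 (-3.61), Ctsl (-3.39), Lamp1 (-3.29), Lipa (-2.14) and Ctsb (-0.98) fell. Of 17 glycolysis and hypoxia genes Pdk1 (1.90), Vegfa (1.79) and Hk1 (1.52) rose, and 0 passed adjusted over the list alone (median 0.28, percentile 69.3, floored 0.13). Of 10 p53 and apoptosis genes Bcl2l1 (-4.70), Cdkn1a (-3.28), Bcl2 (-2.41) and Fas (-1.498) fell and Pmaip1 rose by 1.45 (3 up and 4 down adjusted over the list alone; median -0.20, percentile 18.8, floored -0.09). Of the lists outside the central 95% of random lists on average, the flippase, integrated stress response and inflammatory lists lay inside it on day 6 taken alone, and the LXR list on day 3.

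In all, 1532 genes were higher and 1343 lower with RANKL by limma (4061 had an unadjusted p under 0.05, against 543.55 by chance). On both days, 1276 genes were at least 2-fold higher and 1081 at least 2-fold lower, against 393.3 and 315.1 for independent days, and the differences of the 2 days correlated across genes at 0.789 (0.633 by rank). The counts depended on single arrays: without the M-CSF array of day 3 they were 2346 and 2199, without that of day 6 2443 and 2072, and without the M-CSF+RANKL array of day 3 679 and 569 or of day 6 689 and 509.

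Whether the PSS1 cultures carried the transgene was read from Ptdss1. Its log2 signal was 18.91 and 18.06 in the PSS1-WT culture on days 3 and 6, and 18.79 and 17.50 in the PSS1-LMS culture, against 9.56 and 10.36 in the M-CSF+RANKL culture. The average difference was 369-fold for PSS1-WT (8.53 ± 0.37, adjusted p = 3.02e-09) and 291-fold for PSS1-LMS (8.18 ± 0.37, adjusted p = 5.58e-09). The 2 PSS1 cultures differed by -0.34 (adjusted p = 0.882).

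The second comparison asked what wild-type PSS1 changed in cells with RANKL. By limma only Ptdss1 passed; the next smallest adjusted p was 0.1005, for Mustn1, a small nuclear protein gene of muscle and bone (-1.68 ± 0.28). The osteoclast genes Nfatc1 (0.08) and Dcstamp (-0.25) did not pass. Neither did Acp5 (-0.06), Ctsk (-0.11) and Mmp9 (-0.15), but their signals lay at 19.39 or above in every array with RANKL, so near the ceiling that they leave little room for a rise. Ptdss2 (-0.03) and Pisd (-0.29) did not pass either. In cholesterol synthesis 17 of 18 members were lower and the median was -0.58 (percentile 0, floored -0.24, and 4 of 18 members at or under 7.13 in the arrays compared). None passed over all genes, and 7 fell and none rose adjusted over the list alone, among them Stard4, a sterol carrier (-1.24 ± 0.25, at least 2.03-fold lower), Idi1 (-1.05), Insig1 (-1.02) and Fdps (-0.92).

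Of 5 genes at least 2-fold higher on both days, the others besides Ptdss1 were Cd36, a scavenger receptor that also binds phosphatidylserine (1.52 ± 0.30, adjusted p = 0.340), Il1rapl2 and Samt4, both within background, and a predicted gene. Of 8 genes at least 2-fold lower on both days, the rule named Mustn1, Stard4, the chemokine receptor Ccr2 (-1.21, at least 1.03-fold), the volume-regulated anion channel subunit Lrrc8d (-1.12 ± 0.25, adjusted p = 0.364), and Speer4e and Olfr1199, both within background. After centring on array medians, 8 genes were 2-fold higher and 3 lower on both days. Of the other lists, 5 had medians under the central 95% of matched random lists: dendritic cell and MHC class II (-0.41, percentile 0.545, floored 0.00), vacuolar ATPase (-0.30, 0.16), mitochondrial respiration (-0.27, 0.285, floored -0.24), osteoclast resorption (-0.27, 1.5) and glycolysis and hypoxia (-0.24, 1.76, floored -0.18). Over the range lay the flippases and scramblases (0.18, percentile 99.5, floored 0.00, and -0.04 on day 3) and the single B cell gene Blnk (0.52, percentile 98.3). In these 7 lists no member passed in either adjustment. The vacuolar ATPase, mitochondrial and resorption lists rose with RANKL, and genes higher with RANKL as a whole had medians of -0.19 on day 3 and -0.22 on day 6. The random lists were not matched on that response. Only cholesterol synthesis lay outside the range on each day taken alone; the vacuolar ATPase, mitochondrial and resorption lists lay inside it on day 6, glycolysis and hypoxia on day 3, and the dendritic cell, flippase and B cell lists on both. The median of the phosphatidylserine synthesis list (-0.16) had the opposite sign of its mean (0.53), since Ptdss1 is a member. Adjusted over the list alone, Cd36 rose in the phosphatidylserine recognition list and the protease gene Ctsl by 0.96 in the lysosome list, chosen after its value was seen.

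An unadjusted p under 0.05 was reached by 746 genes against 543.55 by chance, and the 2 days' differences correlated across genes at 0.0657 (0.018 by rank). Without the M-CSF+RANKL array of day 3 the test gave 12 higher and 49 lower genes, without that of day 6 1 and 2, without the PSS1-WT array of day 3 6 and 17 or of day 6 3 and 3, and without either PSS1-LMS array 7 and 11. A filter at the 70th percentile, a filter on the mean of the compared arrays and eBayes with a trend each gave 1 lower gene.

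**Figure D2:**
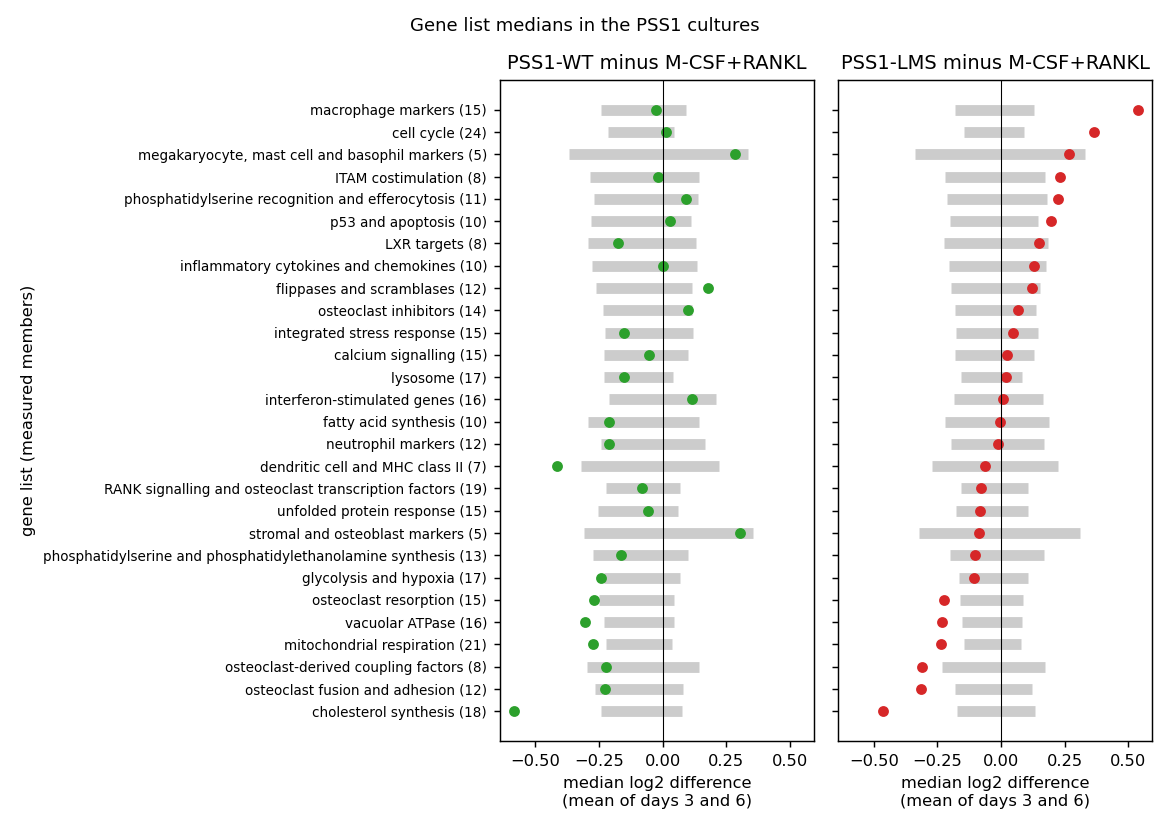
Median log2 difference of 28 gene lists with at least 5 measured members, PSS1-WT (left) and PSS1-LMS (right) minus M-CSF+RANKL, averaged over days 3 and 6; grey bars span the central 95% of 10000 matched random lists. Cholesterol synthesis lay lowest in both panels (-0.58 and -0.46), and macrophage markers highest with PSS1-LMS (0.54). With signals raised to background they did not: cholesterol synthesis had -0.24 and -0.19, above the vacuolar ATPase list at -0.30 and -0.23, and macrophage markers 0.24, below the cell cycle list at 0.36.

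The third comparison asked what mutant PSS1 changed in cells with RANKL. By limma 17 genes rose and 2 fell, and all 19 were also at least 2-fold apart on both days. In simulated data for this comparison, 19 of 164 calls fell on unchanged genes, more than the threshold allows on average. Besides Ptdss1, the largest rises were in Pmp22, a membrane protein gene (4.30-fold, 2.10 ± 0.31, adjusted p = 0.0256), Cd36 (1.90 ± 0.30, adjusted p = 0.0332), the interleukin-7 receptor Il7r (1.72 ± 0.27, adjusted p = 0.0332), the chemokine Ccl3 (1.65 ± 0.30, adjusted p = 0.0348) and Trem2, a lipid-sensing receptor of macrophages and osteoclast precursors (1.59 ± 0.26, adjusted p = 0.0348). Mustn1 fell (-1.54 ± 0.28, adjusted p = 0.0348), as did Olfr1199, whose signals lay within background. The osteoclast genes Nfatc1 (-0.03) and Dcstamp (-0.21) did not pass, nor did Ptdss2 (-0.48) or Pisd (-0.08). Acp5 (-0.04), Ctsk (-0.08) and Mmp9 (-0.10) did not pass either, again from signals near the ceiling.

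The other 11 genes that rose, chosen after their values were seen, were Fcgr3, Igf1, Cd81, Slamf7, Mmp12, Clec4d, Mmp8, Ncf1, Bhlhe41, Sirpb1c and Tlr13, with differences from 1.31 for Tlr13 to 1.51 for Fcgr3. Each of the 16 genes that rose besides Ptdss1 was lower with RANKL in the first comparison, which is expected in part, because the M-CSF+RANKL arrays enter the 2 comparisons with opposite sign. The other genes at least 2-fold lower on both days were Fdps (-1.25, adjusted p = 0.168, at least 1.61-fold), Akap13 (-1.02, adjusted p = 0.191) and a small RNA gene.

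The macrophage marker list was higher, with a median of 0.54 (percentile 100, floored 0.24, and 5 of 15 members at or under 7.13 in the arrays compared). No member passed over all genes, and 5 rose adjusted over the list alone, led by the lysozyme Lyz2 (1.04), the mannose receptor Mrc1 (1.03), the scavenger receptor Msr1 (0.96) and Mertk (0.84). Of 24 cell cycle genes 23 were higher (median 0.36, percentile 100), and Tpx2 (1.10) alone passed adjusted over the list alone. The macrophage and cell cycle lists were lower with RANKL, as were the ITAM and phosphatidylserine recognition lists below. Genes lower with RANKL as a whole had medians of 0.14 on day 3 and 0.18 on day 6. The random lists were not matched on that response. Cholesterol synthesis was again lower in 17 of 18 members (median -0.46, percentile 0, floored -0.19), with Fdps alone past the threshold adjusted over the list alone. Several lists of osteoclast function were lower by small amounts: fusion and adhesion (-0.32, percentile 0.03, none passing), coupling factors (-0.31, percentile 0.39, floored -0.12), vacuolar ATPase (-0.23, percentile 0.14, none passing) and resorption (-0.22, percentile 0.215). The RANK signalling and transcription factor list lay within the range (-0.08, percentile 22.15). Genes higher with RANKL as a whole had a median of -0.16 on each day, and the random lists were not matched on that response. Adjusted over the list alone, Slc4a2 (-0.87) and Car2 (-0.85) fell in the resorption list, and Sphk1 (-0.98), Lif (-0.76) and Pdgfb (-0.64) fell and Hgf rose by 0.72 in the coupling list. Mitochondrial respiration was lower in 20 of 21 members (median -0.24, percentile 0.05, none passing). Fcgr3 and Trem2 rose in the ITAM list in both adjustments (median 0.23, percentile 99.2, floored 0.03). In the phosphatidylserine recognition list (0.22, percentile 99.1, floored 0.00) Cd36 rose in both, and Mertk and Lrp1 (0.75) adjusted over the list alone. In the p53 and apoptosis list (0.20, percentile 99.4, floored 0.18) Cdkn1a (1.02) and Mdm2 (0.81) rose and Pmaip1 (-0.95) fell adjusted over the list alone. The single genes Blnk (0.66, percentile 97.8) and Cd4 (0.65, percentile 98.5, floored 0.00) of the B cell and T and NK cell lists did not pass over all genes. A list of 1 gene leaves nothing to adjust over, and Cd4 lay at or under 7.13 in the arrays compared. The phosphatidylserine synthesis list again had a median (-0.10) and a mean (0.50) of opposite sign. Of the lists outside the range, only the macrophage, cell cycle, cholesterol synthesis and vacuolar ATPase lists lay outside it on each day taken alone. The fusion (-0.08 on day 6), resorption (-0.13), mitochondrial (-0.07) and T and NK cell lists lay inside it on day 6, the ITAM list on day 3, and the coupling, phosphatidylserine recognition, p53 and B cell lists on both days.

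An unadjusted p under 0.05 was reached by 714 genes, and the 2 days' differences correlated across genes at 0.109 (0.034 by rank). On both days 30 genes were at least 2-fold higher and 5 lower, against 1.98 and 1.26 for independent days. In opposite directions, 5 genes were 2-fold higher on day 3 and lower on day 6, and 1 was lower and then higher. Calls other than Ptdss1 ended with quantile normalisation, all 8 arrays in the fit, or no day term, which each left 1 higher and 0 lower, and all but 1 ended with no filter, which left 2 and 0, while a 70th percentile filter gave 33 and 4 and eBayes with a trend 37 and 6. Without the M-CSF+RANKL array of day 3 the counts were 52 and 31, without that of day 6 14 and 4, without either PSS1-WT array 47 and 12, without the PSS1-LMS array of day 3 32 and 13 and without that of day 6 7 and 4.

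The fourth comparison set mutant against wild-type PSS1, the contrast that shares no array with the RANKL effect. By limma 0 genes passed, 773 had an unadjusted p under 0.05 against 543.55 by chance, and the smallest adjusted p was 0.0792. That value belonged to Akap13, a kinase anchor (3.06-fold lower with PSS1-LMS, -1.61 ± 0.24), and to the tetraspanin Cd81 (1.55 ± 0.25). Macrophage markers were higher with PSS1-LMS in 12 of 15 members (median 0.57, percentile 100, floored 0.29). None passed over all genes and 7 passed adjusted over the list alone, led by C1qb (1.53 ± 0.29), Ly86 (0.78), Lyz2 (0.73) and Mrc1 (0.70). The macrophage list was lower with RANKL, a response on which the random lists were not matched. Genes lower with RANKL by a mean log2 gap of 4 to 6 had a median of 0.40 in this comparison. Those with a gap of 6 to 8 had 0.60. Averaged over both days, osteoclast resorption genes showed no common shift (median 0.01, percentile 20.6, mean -0.04), nor did the RANK signalling list (median -0.00, mean 0.04) or the vacuolar ATPase list (0.10, percentile 69.2). None of their members passed in either adjustment. Acp5, Ctsk and Mmp9 lay near the ceiling in these arrays and could show little of a rise. The fusion and adhesion list had -0.20 on day 3 (percentile 0.07) and 0.07 on day 6 (percentile 52.2), with no member passing in either adjustment.

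On both days 11 genes were at least 2-fold higher with PSS1-LMS and 2 at least 2-fold lower, against 1.68 and 0.552 for independent days. In opposite directions, 1 gene was 2-fold higher on day 3 and lower on day 6, and 2 were lower and then higher. The counts in the same direction were 4 and 5 after centring on array medians and 7 and 2 after quantile normalisation. The largest were Pmp22 (1.59 ± 0.31, adjusted p = 0.186), Cd81, C1qb (adjusted p = 0.186), the endocytic adaptor Dab2 (1.36, adjusted p = 0.186), the glutathione transferase Mgst1 (1.31, adjusted p = 0.252) and the RNA-binding protein gene Celf2 (1.26, adjusted p = 0.186). The lower genes were Akap13 and the ATP-gated channel P2rx5 (-1.34 ± 0.29, adjusted p = 0.252). Further lists over the central 95% of random lists were cell cycle (0.37, percentile 100, floored 0.35, none passing), inflammatory genes (0.37, percentile 99.8, floored 0.15), neutrophil markers (0.32, percentile 99.8, floored 0.05), LXR targets (0.31, percentile 98.3, floored 0.11, none passing) and lysosome (0.28, percentile 99.9, none passing). Adjusted over the list alone, Ccl3 (1.496) rose among the inflammatory genes, and Lcn2 (1.01) and Mmp8 (0.95), both of neutrophil granules, among the neutrophil markers. The ITAM list lay within the range (0.26, percentile 96.9), and Fcgr3 (1.37) and Trem2 (1.12) rose in it adjusted over the list alone. No list lay under the range on average. The cell cycle, inflammatory and LXR lists were also lower with RANKL, a response on which the random lists were not matched. Only macrophage markers lay over it on each day taken alone; the cell cycle, neutrophil and LXR lists lay inside it on day 6, the inflammatory list on day 3 and the lysosome list on both.

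The 2 days' differences correlated across genes at 0.163 (0.159 by rank). The count of 0 changed with the fit: 38 higher and 10 lower without the PSS1-WT array of day 3, 32 and 4 without either M-CSF+RANKL array, 19 and 7 without the PSS1-LMS array of day 3, 3 and 1 without that of day 6, 0 and 0 without the PSS1-WT array of day 6, 7 and 1 with a 70th percentile filter, 6 and 1 with eBayes with a trend, and 1 and 1 with a filter on the mean of the compared arrays. Centring on array medians moved the median of all genes in this comparison on day 3 from 0.06 to -0.05, a change of -0.11, and no filter moved that of the RANKL effect on day 3 from 0.04 to -0.07, also by -0.11; no list of at least 5 genes outside the central 95% of random lists changed the direction of its median under either setting.

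The next question was whether genes that respond to RANKL shifted together in the PSS1 cultures. Genes higher with RANKL were slightly lower in both PSS1 cultures than in the M-CSF+RANKL culture. Their median difference was -0.19 on day 3 and -0.22 on day 6 with PSS1-WT, and -0.16 on both days with PSS1-LMS, over 2036 genes on day 3 and 2100 on day 6 (percentile 0 each). Genes lower with RANKL were higher with PSS1-LMS, by 0.14 on day 3 and 0.18 on day 6 over 1918 and 1786 genes (percentile 100 each); with signals raised to background these medians were 0.01 and 0.13, so little of the shift on day 3 remained. With PSS1-WT the median of these genes was -0.02 on day 3 and 0.06 on day 6, also at percentile 100 each, and 0.00 on both with signals raised to background. On day 3, 48.3% of them were higher with PSS1-WT, against 40.1% of the other genes, and on day 6 55.4% against 43.1%. The sign on day 3 is not settled, with 0.03 after quantile normalisation and 0.08 after centring on array medians, which adds the same 0.096 to every gene there.

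Between the PSS1 cultures, the 1081 genes at least 2-fold lower with RANKL on both days were higher with PSS1-LMS by a median of 0.22 on day 3 and 0.17 on day 6 (percentile 100 each). On day 3, 73.0% of them were higher, against 55.0% of all other measured genes, and on day 6 66.2% against 52.0%. The 1276 genes higher with RANKL had medians of -0.01 and 0.02 (percentiles 0 and 0.18), and on day 6 -0.05 after centring on array medians. With signals raised to background, the medians of the 1081 genes were 0.15 and 0.09, and centring on array medians gave 0.11 on each day.

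**Figure D3:**
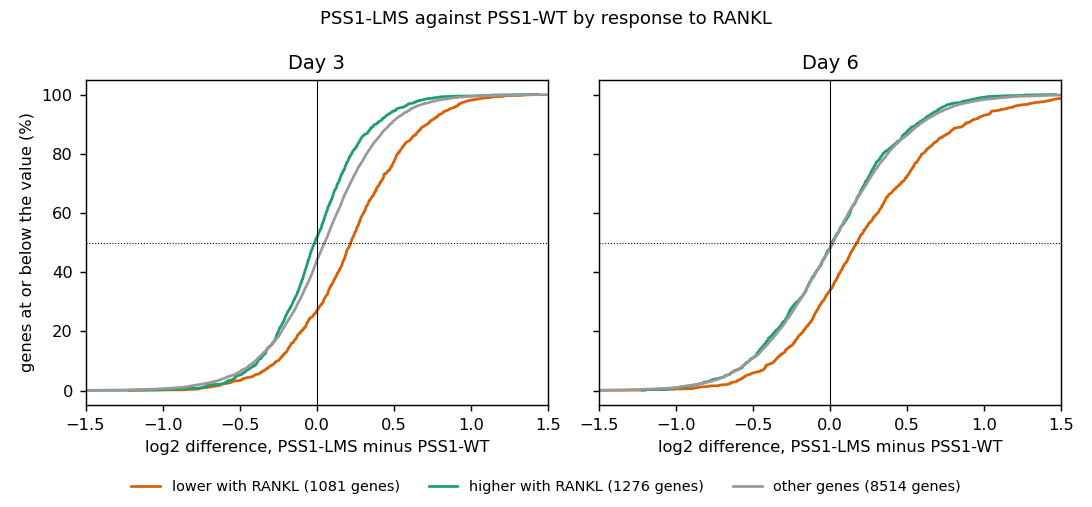
Cumulative percentage of genes at or below each log2 difference between PSS1-LMS and PSS1-WT on days 3 and 6, for genes lower with RANKL (1081), genes higher with RANKL (1276) and the other 8514. The curve of the genes lower with RANKL lies to the right, with medians of 0.22 and 0.17.

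The last comparison set day 6 against day 3 across the 4 cultures. The 6 genes named for the largest falls fell in every culture: Ngp fell at least 219-fold (-8.41 ± 0.20, adjusted p = 2.35e-06), Lcn2 at least 270.3-fold (-8.29 ± 0.30), S100a9 at least 40.2-fold (-6.08 ± 0.28), Chil3 at least 28.7-fold (-5.88 ± 0.30), S100a8 at least 27.8-fold (-6.21 ± 0.41) and the monocyte marker Ly6c2 at least 6.74-fold (-4.99 ± 0.25). Acta2, smooth muscle actin, rose 13.1-fold (3.71 ± 0.30, adjusted p = 0.00243), the macrophage elastase Mmp12 7.75-fold (2.95 ± 0.36, adjusted p = 0.02505), the matrix genes Sparc at least 2.39-fold (2.65 ± 0.29) and Tnc at least 1.76-fold (2.35 ± 0.25), and Cd36 5.55-fold (2.47 ± 0.35, adjusted p = 0.0455). The 6 genes that fell and Acta2 stayed past the threshold in all 17 alternatives, Sparc in 11, Mmp12 and Tnc in 10 each and Cd36 in 7, and Tmem176b (2.49, adjusted p = 0.0634) did not pass.

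Of 12 neutrophil markers 9 fell (10 adjusted over the list alone; median -2.61, percentile 0, floored -0.07). Of 15 integrated stress response genes 3 fell, namely Asns (-2.16), Aldh18a1 (-1.84) and Psat1 (-1.81), and 9 fell and 1 rose adjusted over the list alone (median -1.03, percentile 0, floored -0.50). Of 5 stromal and osteoblast markers Sparc rose, and 4 did adjusted over the list alone (median 0.73, percentile 100, floored 0.00). Macrophage markers had a median of 0.48 (percentile 100, floored 0.29), with none past the threshold over all genes and 6 adjusted over the list alone. Their median was 0.99 in the M-CSF culture and 0.38 over the cultures with RANKL, or 0.58 and 0.00 with signals raised to background. In the phosphatidylserine recognition list (0.50, percentile 99.99, floored 0.28) Cd36 rose, and Gas6 (2.15) too adjusted over the list alone. The unfolded protein response (-0.50) and glycolysis and hypoxia (-0.45) lists lay at percentile 0 with no member passing in either adjustment. None of the always named genes passed over the 8 arrays; Ptdss1 differed by -0.33. Nfatc1 fell in the M-CSF+RANKL (-0.90), PSS1-WT (-0.99) and PSS1-LMS (-1.07) cultures and rose in the M-CSF culture (1.82), and with the 6 arrays with RANKL alone it passed (-0.99 ± 0.20, adjusted p = 0.0116).

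By limma 11 genes rose and 20 fell, and 863 had an unadjusted p under 0.05; 16 genes were at least 2-fold higher and 26 lower in all 4 cultures. The M-CSF culture changed most, with 1622 genes at least 2-fold higher and 1406 lower, against 197 and 229 in the M-CSF+RANKL, 232 and 393 in the PSS1-WT and 183 and 280 in the PSS1-LMS culture. With the 6 arrays with RANKL alone, or without either M-CSF array, 142 genes rose and 225 fell; without any 1 of the M-CSF+RANKL or PSS1-WT arrays 1 and 9, and without a PSS1-LMS array 1 and 10. A 70th percentile filter gave 6 higher genes, a filter on the mean of the compared arrays 7 and a fit without culture 3.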

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

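The scaling tests and the test of a general fall of genes lower with RANKL were chosen only after the result was seen, as were the medians of cholesterol synthesis genes above 7.13 and with signals raised to it. The differences in this paragraph were not tested. Cell cycle genes moved in opposite directions with time: their median difference between day 6 and day 3 was 0.28 over the cultures with RANKL (0.21 in M-CSF+RANKL, 0.40 in PSS1-WT and 0.18 in PSS1-LMS) and -1.63 in the M-CSF culture. S100a8 was higher with RANKL on day 3 (1.16) and lower on day 6 (-1.56), when its signals lay within background in every culture. Among 1269 measured transcript clusters without a gene symbol, which no comparison used, 92 were at least 2-fold higher and 88 at least 2-fold lower with RANKL on both days, against 26.1 each for independent days.

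Genes lower with RANKL were higher in the PSS1-LMS than in the PSS1-WT culture, by a median of 0.22 on day 3 and 0.17 on day 6. Centring on array medians changed every gene's difference by -0.11 on day 3 and -0.06 on day 6, so part of the distance from 0 goes with scaling. The tables argue against a scaling difference as the whole cause, since after quantile normalisation the medians were 0.18 and 0.19, both at percentile 100 of matched random lists. Whether an equal share of cells stayed like the M-CSF culture was examined as well. A share of 1.07%, set by 144 genes with a log2 gap of 4 to 6, predicted 2.30 for the 10 genes with a gap over 8. There 0.52 was observed (ratio 0.225, 95% bootstrap interval 0.0829 to 0.343). The bootstrap resampled genes, so its interval leaves out spread between arrays or cultures. For 46 genes with a gap of 6 to 8 the share predicted 0.90, where 0.60 was observed. On a linear scale these values fall short of an equal share, but that the scale is linear was not checked. Genes with a gap over 8, such as Fcrls and C1qa, also lay within background in both PSS1-LMS arrays. An equal share thus stays open, as do unequal or delayed mixtures. So does a PSS1-LMS culture less far along in time: 197 genes rising with time in the M-CSF+RANKL culture had a median of 0.0543, not below 0, but at percentile 76.6. Of these, 48 are themselves lower with RANKL (median 0.35), and the other 149 had a median of 0.00 at percentile 19.5; the 229 falling genes had 0.11, at percentile 99.85. The mutation itself is the biological explanation that the design names, and it remains untested with 1 culture of each kind.

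Genes higher with RANKL were lower in both PSS1 cultures than in the M-CSF+RANKL culture. Compression of bright signals near the ceiling is argued against, because without genes brighter than a log2 value of 14 the 4 medians were -0.19, -0.21, -0.14 and -0.17, each at percentile 0. A scaling difference as the whole cause is argued against by medians of -0.11, -0.20, -0.12 and -0.14 after quantile normalisation, also at percentile 0 each. The M-CSF+RANKL arrays shared by both comparisons and the retroviral infection itself stay open, as does PSS1, which was not tested apart from them.

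Cholesterol synthesis genes were lower in both PSS1 cultures than in the M-CSF+RANKL culture. A general fall of genes lower with RANKL is argued against: the list's medians were -0.29 and -0.65 with PSS1-WT and -0.36 and -0.52 with PSS1-LMS on days 3 and 6, where other genes lower with RANKL had -0.02, 0.07, 0.14 and 0.18. Signals near background are argued against as the whole cause, since the 13 members above the background of each array with RANKL had medians of -0.28, -0.68, -0.33 and -0.81, and the 10 members above 7.13 in all of these arrays -0.46, -0.74, -0.39 and -0.73. With signals raised to 7.13 the medians of all 18 members over both days shrank from -0.58 to -0.24 and from -0.46 to -0.19. A single explanation for both cultures could lie in the shared M-CSF+RANKL arrays or in the infection, and neither was tested. A response to PSS1 activity, wild-type or mutant, is the biological explanation and stays a hypothesis.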

How the results depend on the processing

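The alternative that raises signals to background was chosen only after the result was seen. The cause was not tested for any of the changes below, except that fewer or more genes or arrays enter by construction where a filter, a fold threshold or a set of arrays changed. Over all alternatives other than leaving out an array, 185 gene counts stayed within 1.5 times, 57 were larger and 30 smaller; 569 values of named genes kept their side of the threshold, 17 newly passed and 33 no longer passed, none turning direction while past it. Of the list medians 389 stayed within the spread of random lists, 64 moved and 3 reversed, and of the medians of RANKL-responsive genes 46 stayed, 34 moved and 4 reversed. Taking the mean of all clusters of a gene changed none of its 180 values beyond these limits. Only 55 of 19505 genes had several clusters, so this setting could change little. On day 3 alone the flippase list in the PSS1-WT effect (-0.038) and the LXR list in the RANKL effect (0.20) reversed, and on day 6 alone the inflammatory list in the RANKL effect (0.29). A 1.5-fold threshold gave, higher and lower on both days, 1957 and 1690 genes for RANKL, 50 and 102 for PSS1-WT, 147 and 76 for PSS1-LMS, 156 and 56 for PSS1-LMS against PSS1-WT, and 57 and 68 for the day effect. With the 70th percentile filter PSS1-WT had 2 genes 2-fold higher on both days and 1 lower gene past the threshold, PSS1-LMS 33 and 4 past it, PSS1-LMS against PSS1-WT 7 and 1, and the day effect 6 higher; genes lower with RANKL had a median of 0.20 with PSS1-LMS on day 6. With the filter on the mean of the compared arrays, PSS1-WT had 2 genes 2-fold higher on both days and 1 lower past the threshold, PSS1-LMS 26 higher, PSS1-LMS against PSS1-WT 1 and 1, and the day effect 7 higher. With no filter PSS1-LMS had 2 and 0 past the threshold, and PSS1-LMS against PSS1-WT 6 genes 2-fold lower on both days. With eBayes with a trend PSS1-WT had 1 lower gene, PSS1-LMS 37 and 6, and PSS1-LMS against PSS1-WT 6 and 1. All 8 arrays in the fit, no day term and quantile normalisation each left 1 and 0 for PSS1-LMS, and no culture term left 3 higher for the day effect; with the 6 arrays with RANKL it had 142 and 225. Centring on array medians gave 8 and 3 genes 2-fold apart on both days for PSS1-WT and 4 and 5 for PSS1-LMS against PSS1-WT, and quantile normalisation gave 7 higher for the latter. Centring adds the same amount to every gene of a comparison on a day, so a median near 0 that changes sign by it tells nothing of these genes apart from the others. For genes higher with RANKL, centring gave -0.10 and -0.13 with PSS1-WT, -0.14 with PSS1-LMS on day 6, and -0.12 and -0.046 (reversed) for PSS1-LMS against PSS1-WT; for genes lower with RANKL it gave 0.076 (reversed) and 0.15 with PSS1-WT, 0.20 with PSS1-LMS on day 6, and 0.11 and 0.11 between the PSS1 cultures. Quantile normalisation gave -0.11 and -0.20 with PSS1-WT, -0.12 with PSS1-LMS on day 3 and -0.054 between the PSS1 cultures on day 3 for the higher genes, and 0.026 (reversed), 0.16 and 0.18 on day 3 for the lower genes in the same order. Choosing genes at 4-fold gave, for the higher genes, -0.23 and -0.25 with PSS1-WT, -0.25 and -0.22 with PSS1-LMS and -0.057 between the PSS1 cultures on day 3; for the lower genes it gave 0.029 (reversed) and 0.13, 0.24 and 0.35, and 0.25 and 0.31. With signals raised to background the higher genes gave -0.17 and -0.13 with PSS1-LMS and -0.038 between the PSS1 cultures on day 3, and the lower genes 0.00 and 0.00 with PSS1-WT, 0.012 and 0.13 with PSS1-LMS, and 0.15 and 0.094 between the PSS1 cultures. Leaving out each array in turn gave 679 to 2443 higher and 509 to 2199 lower genes for RANKL, 1 to 12 and 2 to 49 for PSS1-WT, 7 to 52 and 4 to 31 for PSS1-LMS, 0 to 38 and 0 to 10 for PSS1-LMS against PSS1-WT, and 1 to 142 and 9 to 225 for the day effect; the array left alone in its culture is assumed to vary like the others. Raising signals to background shrinks differences by construction, because members under 7.13 become equal. Of 16 interferon-stimulated genes, 15 lay at or under 7.13 in the arrays of each PSS1 comparison, so the raised medians say little of that list there. The offset of 32 for linear values was not run, as the values were already log2. No paired analysis was possible because each group is 1 array without a replicate number; arrays are matched only by day and culture, which are terms of the fit.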

Other observations

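The limit to splits with 1 array of every culture on each side, in the test of splits below, was chosen only after the result was seen. The M-CSF culture without RANKL changed between days 3 and 6 in ways that the cultures with RANKL did not show at the same size; the differences between cultures were not tested. The median difference of LXR targets was 2.44 in the M-CSF culture and -0.11 over the cultures with RANKL. Pltp, a phospholipid transfer protein, had 10.72 against 0.54, and Abca1, a cholesterol exporter, 4.88 against -0.06. Inflammatory genes had -1.81 against 0.06. Interferon-stimulated genes had 1.64 against 0.03 and the resorption list 1.09 against -0.07, but with signals raised to background both rises in the M-CSF culture were 0.00, with 10 of 16 and 7 of 15 members within background on both days, so they rest on signals near background. None of these 4 lists had a member past the limma threshold over all genes in the day comparison; adjusted over the list alone, Smpdl3a of the LXR list passed (1.24). The M-CSF values rest on 1 array per day.

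The integrated stress response list, which covers amino acid synthesis and import, was lower on day 6 in both kinds of culture: its median was -0.86 in the M-CSF culture and -1.10 over the cultures with RANKL, or -0.86 and -0.38 with signals raised to background. The neutrophil marker list was lower in both too, at -2.50 and -2.69, or 0.00 and -0.09 with signals raised to background. The phosphatidylserine recognition list was higher in both, at 0.69 and 0.31, or 0.69 and 0.06 with signals raised to background.

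Whether the genes that passed between day 6 and day 3 could arise from any grouping of the arrays was examined by splitting the 8 arrays into 4 and 4 in every other way. Of 35 splits, 3 followed the cultures and could not be fitted. Only 8 of the other 32, the real one among them, put 1 array of every culture on each side, and the rest confound the split with culture in part. Of these 8 splits, 1 gave as many genes past the threshold, the real one with 31, and the highest of the others gave 0; the splits are too few for a share under 0.05. Anything else that the arrays of a day shared goes with time in culture.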
